A study of Mus musculus with 12 samples.

How the data were processed

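Newly made RNA was measured in 12 samples of mouse macrophages, 3 in each of 4 groups: bone marrow-derived macrophages (BMM) and the fetal liver-derived MPI-2 line, each mock-treated or given LPS. Per the labels' protocols, BMM grew in DMEM and MPI-2 in RPMI, both with 10% fetal calf serum, the first with M-CSF and the second with GM-CSF. RNA was marked with 4-thiouridine for 60 min, biotinylated and purified, and 200 ng of it was amplified for whole-transcript arrays. In the LPS groups, per the labels' treatment protocol, labelling began 30 min after LPS and so ended at 90 min. Purified newly made RNA shows transcription within the labelling window with little of the older RNA, so a change need not equal that of total RNA.

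The deposited table holds 1 log2 expression value per probe set and array. Per the submitters' processing notes it was made with RMA and the package affy, whose versions are not given in the sources used here. RMA corrects background, forces the probes of all arrays in a run to the same distribution and summarises each probe set by median polish. Whether all 12 arrays went through it in 1 run is not given in the sources used here, and the log base was taken as 2 from the method and the range of the values (1.18 to 12.82). Quantile normalization removes any overall change in the amount of newly made RNA, so all differences are relative to the other genes of an array. The arrays had medians of 3.60 to 3.79 on the log2 scale. Arrays give no read depth, and their number limits the precision.

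Of 34760 probe sets, 21640 name 1 gene in the platform annotation, 1321 name several and 11799 are unnamed here. Probe sets naming several genes were not used to name any gene. Symbols were updated through Entrez identifiers against the RefSeq annotation of GRCm38.p6, which matched 19855 symbols and was used for names alone. Where a gene had several probe sets (954 genes), the probe set with the highest mean over the 12 arrays stood for it, which left 19937 genes. The background level, 3.37, is the 95th percentile of the mean values of 1027 olfactory receptor genes, and 12030 genes lay above it. No gene was filtered out before the tests. No 2 arrays held identical values.

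Groups were taken from the sample labels. A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and 6.99 added by the empirical Bayes step. From it came 5 comparisons: LPS against mock in BMM, the same in MPI-2, the difference of those responses (MPI-2 minus BMM), and MPI-2 against BMM in mock and in LPS. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05, and every adjusted p of a single gene is limma's. The comparison and its tests, 28 gene lists and the rule for naming genes were fixed before the data were examined. Of 813 list entries 721 matched a tested gene. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists of a comparison, and again with the correlation between genes estimated from the data. Limma's fry, planned beside camera, tests whether the members of a list changed, without comparing them with other genes. It passed lists that camera did not. A list said to pass or not to pass did so by camera unless fry is named. Of 49 list calls 21 held with the estimated correlation, namely 5 of 11 for LPS in BMM, 4 of 10 for LPS in MPI-2, 1 of 4 for the difference, 6 of 12 for mock and 5 of 12 for LPS between cell types.

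Genes are named by rule. Clone names, predicted genes, microRNA, small nucleolar RNA, and olfactory, vomeronasal and antigen receptor families were left out. Except for the difference of responses, all 3 arrays of a group had to lie above all 3 of the other. For each comparison the genes with the 10 largest increases and the 10 largest decreases past the threshold are given, in part, in order of size. Added to these are up to 4 members of each described list with the smallest adjusted p, any member that went against its list, both given in part as well, and a fixed set of macrophage genes. Histone genes and other families of near-identical copies can share probes, and antisense transcripts such as Il1bos overlap a coding gene.

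The fit was tested on simulated data with 200 changed genes among 19937. Of genes changed by log2 1 it recovered 95.5% for LPS in BMM, 94% for LPS in MPI-2, 64.2% for the difference of responses, 98.5% for mock and 98.5% for LPS between cell types. Of genes changed by log2 0.5 it recovered 16.4%, 20.9%, 8.96%, 20.9% and 23.9%, and false calls made up 6%, 2.07%, 6.5%, 3.31% and 9.2% of the calls. The fit shares 1 residual spread per gene, so these rates need not hold for the real calls of either cell type. The real arrays had a median gene SD of 0.176 and 0.204 in BMM mock and LPS, against 0.12 and 0.109 in MPI-2. The simulation also changed a far smaller share of genes than the 13.4% to 44.1% called in the real comparisons. Benjamini-Hochberg adjustment is stricter where few genes change, so recovery in the real data can be higher. Alternatives covered the arrays in the fit, replicate numbers as a block, 2 further scalings between arrays, a filter at the background level, the treatment of several probe sets, the variance model, the threshold and leaving out each array. Leaving out the BMM mock and BMM LPS array least like its group together, quantile normalization of the probe sets, the median shift for the agreement of responses and leaving out single arrays for the gene lists were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.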

Results

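Newly made RNA was profiled in 2 kinds of mouse macrophage, each with and without lipopolysaccharide (LPS), the bacterial cell wall component sensed by Toll-like receptor 4. Bone marrow-derived macrophages (BMM) had been grown from C57BL/6 marrow with macrophage colony-stimulating factor (M-CSF). MPI-2 is a self-renewing macrophage line from fetal liver that depends on granulocyte-macrophage colony-stimulating factor (GM-CSF). Cells took up 4-thiouridine, a uridine analogue built into RNA as it is transcribed, for 60 min, and the labelled RNA was hybridised to whole-transcript arrays. In the LPS cultures labelling began 30 min after LPS, so these samples cover transcription from 30 to 90 min of exposure. The 12 arrays formed 4 groups of 3 (BMM mock, BMM LPS, MPI-2 mock and MPI-2 LPS), a number that limits the precision of every value below. Changes are differences of deposited log2 values with their standard error (SE), and group levels are means with the SD of 3 arrays. The sample titles call the arrays of a group biological replicates without naming separate animals or cultures, so the p-values measure the spread between these samples, part of which may be technical.

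Of 19937 genes tested, 12030 (60.3%) had a mean above 3.37, the background level. It was set by the 95th percentile of 1027 olfactory receptor genes, taken here as mostly silent in macrophages, which was not tested. A log2 change of a gene with a group mean under that level is limited by background and understates the change in RNA, and where only 1 cell type is so limited, the difference of responses can be overstated. Arrays of a group correlated across genes at r of 0.994 to 0.996 in MPI-2 and 0.975 to 0.989 in BMM. The interquartile range of the log2 values was 2.38 to 2.69 in BMM LPS, below the 2.78 to 2.88 of BMM mock, and 2.95 to 3.04 in MPI-2 LPS, below the 3.06 to 3.21 of MPI-2 mock. BMM and MPI-2 arrays also differ in growth factor and medium, and array batch cannot be told apart from cell type.

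**Figure D1:**
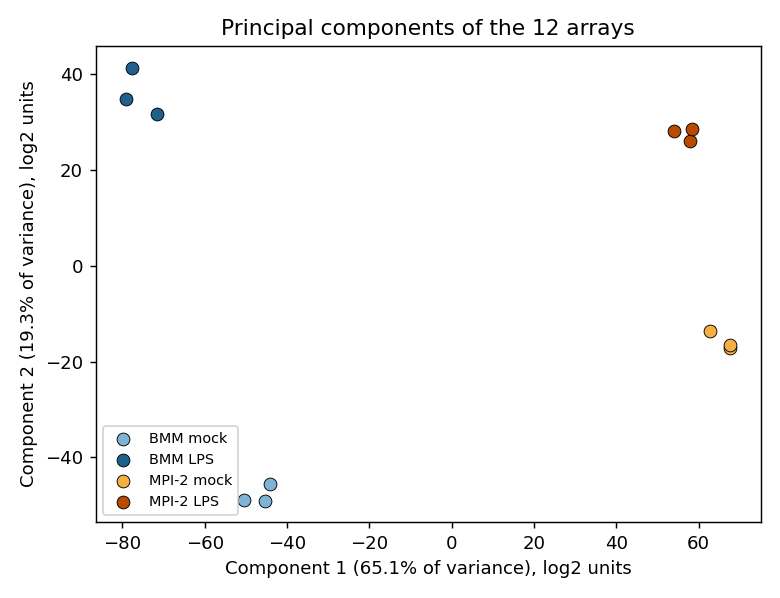
Principal components of the 12 arrays over all genes, with each point an array, coloured by group, and the share of variance on each axis. The first component (65.1%) parts BMM from MPI-2 and the second (19.3%) parts mock from LPS in each.

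The first comparison asked what LPS changes in the RNA made by BMM. The genes with the largest increases included cytokine and interferon genes. Il6, an inflammatory cytokine, had the largest increase that every array shared, log2 7.11 ± 0.24, from 2.76 ± 0.081 (SD, n = 3), a level under background, to 9.87 ± 0.56. The interferon-induced GTPase Gbp5 followed at 6.31 ± 0.14 (SE), the oxysterol-making enzyme Ch25h at 6.22 ± 0.15, interferon beta (Ifnb1) at 6.12 ± 0.24, Il1a at 5.55 ± 0.29 and the protease inhibitor Serpinb2 at 5.34 ± 0.19. The largest decreases were those of the arrestin-domain gene Arrdc3 (-4.39 ± 0.15), the lysophosphatidic acid receptor Lpar6 (-4.17 ± 0.16), Lhfpl2 (-4.08 ± 0.20), the amino acid transporter Slc43a2 (-4.02 ± 0.20) and Cytip (-3.85 ± 0.12). These 11 genes had limma adjusted p from 3.13e-13 to 1.01e-09. BMM mock means of Ifnb1, Serpinb2, Nos2 and Il12b also lay under background.

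The interferon list was the most uniform group. Of its 46 measured members, 45 rose (46 adjusted over the list alone) and none fell, with a median of log2 2.37 and a camera adjusted p of 1.57e-47. Mx2 rose by 5.04 ± 0.14, Gbp3 by 4.34 ± 0.13 and Ifit1, an RNA-binding antiviral protein, by 3.78 ± 0.12. Of 33 NF-kB targets and feedback regulators, 30 rose (30 adjusted over the list alone) and none fell (median 1.39, adjusted p = 2.37e-23). Ptgs2, the inducible prostaglandin synthase, rose by 4.12 ± 0.13, Cd40 by 4.50 ± 0.16 and Traf1 by 2.76 ± 0.12. Among 27 cytokines 24 rose and 1 fell, the same adjusted over the list alone (median 2.41, adjusted p = 6.23e-23). Il12b was higher by 4.57 ± 0.13, Tnfsf15 by 4.01 ± 0.12 and Il27 by 3.94 ± 0.16, while Osm fell, -1.58 ± 0.23. Among 25 chemokines 17 rose and 1 fell, again the same adjusted over the list alone (median 1.22, adjusted p = 1.16e-13). The T cell attractants Cxcl9, at 5.33 ± 0.14, and Cxcl11, at 5.26 ± 0.14, led them, and Cxcl14 fell, -0.74 ± 0.14. These 4 lists kept their call with an estimated correlation.

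Lipid metabolism genes fell in BMM. Of 27 members of the lipid and PPAR list, 15 fell and 1 rose (17 and 2 adjusted over the list alone; median -0.51, adjusted p = 2.32e-05), and the call held with an estimated correlation (adjusted p = 0.0282). The desaturase Scd2 fell, -3.49 ± 0.24, as did the lysosomal lipase Lipa, -1.95 ± 0.13, and Lpcat3 rose by 0.68 ± 0.16. Histone genes fell in 13 of 20 cases (15 adjusted over the list alone) with none higher (median -0.85, adjusted p = 4.81e-07). That call was lost with an estimated correlation (adjusted p = 0.175). H1f2 changed by -3.61 ± 0.16, H2bc8 by -2.49 ± 0.22 and H3c4 by -2.28 ± 0.20, and near-identical histone copies can share probes. Of 54 cell cycle genes 27 fell and 3 rose (30 and 3 adjusted over the list alone; median -0.45, adjusted p = 7.05e-07), against an adjusted p = 0.134 with an estimated correlation. After cyclic loess, a further scaling between arrays, 15 fell and 4 rose. The centromere histone Cenpa fell, -2.56 ± 0.13, with the helicase subunit Mcm7, -1.29 ± 0.11, and the cyclin Ccna2, -1.32 ± 0.12. Mki67 rose by 1.66 ± 0.13, E2f8 by 1.35 ± 0.21 and Mad2l1 by 0.68 ± 0.12.

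Other lists were called in BMM as well. Of 31 Toll-like receptor and sensing genes 15 rose and 3 fell, the same adjusted over the list alone (median 0.36, adjusted p = 0.00117; adjusted p = 0.175 with an estimated correlation). Ikbke rose by 2.55 ± 0.12 and Tlr1 by 1.90 ± 0.12, and Tlr13 fell, -0.97 ± 0.22, with Tlr9, -1.19 ± 0.20, and Tollip, -0.59 ± 0.17. Tollip lost its call without BMM mock replicate 2 (-0.55) or 3 (-0.52) or BMM LPS replicate 3 (-0.38). Polarisation genes rose in 9 of 18 cases with 1 lower, the same adjusted over the list alone (median 0.67, adjusted p = 1.7e-05; adjusted p = 0.0733 with an estimated correlation). Acod1, which makes itaconate, rose by 3.00 ± 0.13 and Nos2, the inducible nitric oxide synthase, by 2.76 ± 0.15, while Tgm2 fell, -0.99 ± 0.16. In the list of genes of M-CSF-grown macrophages 16 of 40 fell and 5 rose (16 and 6 adjusted over the list alone; median -0.25, adjusted p = 0.0112; adjusted p = 0.372 with an estimated correlation and 0.0566 among genes above background). The protease Lgmn fell, -2.91 ± 0.18, with the scavenger receptor Stab1, -2.36 ± 0.18, whereas Vcam1 (4.30 ± 0.15), Fcgr4 (2.27 ± 0.16), Axl (0.83 ± 0.14), Folr2 (1.85 ± 0.17) and Cd14 (0.53 ± 0.13) rose. Among 13 housekeeping genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.0493; adjusted p = 0.372 with an estimated correlation). Gusb fell, -2.81 ± 0.12, with Polr2a, -0.99 ± 0.15, and Pgk1 rose by 0.54 ± 0.12. Camera no longer called the housekeeping list with the replicate numbers of the sample titles as a block (adjusted p = 0.0647). That list's median was -0.10 without BMM LPS replicate 3 (adjusted p = 0.129), and its call was also lost without BMM mock replicate 3 (-0.22, 0.0788), BMM LPS replicate 1 (-0.27, 0.0816), MPI-2 mock replicate 2 (-0.21, 0.0513) or any MPI-2 LPS array (-0.21, 0.0502 to 0.0539), without BMM mock replicate 1 and BMM LPS replicate 3 together (-0.13, 0.12) and among genes above background (-0.21, 0.26).

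Immediate early genes went both ways in BMM. Of 37, 10 rose and 11 fell (11 and 12 adjusted over the list alone; median -0.07, mean 0.06, camera adjusted p = 0.813). Egr2 rose by 1.95 ± 0.13, Csrnp1 by 2.36 ± 0.16 and the phosphatases Dusp2 by 2.93 ± 0.21 and Dusp16 by 1.82 ± 0.14. Other genes fixed for description were Tnf, higher by 1.74 ± 0.14, Il1b, higher by 2.44 ± 0.17, the anti-inflammatory cytokine Il10, higher by 3.77 ± 0.25, and Cxcl10, higher by 2.13 ± 0.17. The lipid-regulating nuclear receptor Pparg fell, -1.05 ± 0.14, with the M-CSF receptor Csf1r, -1.22 ± 0.14, and the shared beta chain of the GM-CSF receptor, Csf2rb, -1.35 ± 0.14. The LPS receptor Tlr4 (-0.39 ± 0.19, adjusted p = 0.153) and the scavenger receptor Marco (0.18 ± 0.16, adjusted p = 0.458) did not pass, though Tlr4 did without BMM LPS replicate 3 (-0.59). In all, 2053 genes rose and 3061 fell, of which 773 and 1050 changed at least 2-fold, and 7017 had an unadjusted p under 0.05. After cyclic loess 2412 rose and 2427 fell, and with the 6 BMM arrays alone 1321 and 2143. The other 17 lists did not pass camera. Fry called some of them, among them colony-stimulating factor signalling as higher (adjusted p = 0.0036) and macrophage transcription factors as lower (0.0132). The macrophage transcription factor list (6 higher, 15 lower of 40; adjusted p = 0.0811) passed without BMM mock replicate 2 (0.03) or BMM LPS replicate 2 (0.0277), and that of colony-stimulating factor signalling (9 and 7 of 27; adjusted p = 0.147) without BMM LPS replicate 3 (0.0231), alone or together with BMM mock replicate 1 (0.00696). Leaving out BMM mock replicate 1 and BMM LPS replicate 3 together, the arrays least like the rest of their groups, brought the immediate early list to 15 higher and 9 lower (median 0.25, adjusted p = 0.0453).

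The second comparison asked what LPS changes in MPI-2. Il6 again had the largest increase, log2 6.79 ± 0.24 (SE), from 3.87 ± 0.4 to 10.7 ± 0.24 (SD, n = 3). The collagenase Mmp13 rose by 5.78 ± 0.14, Il1f6, the cytokine IL-36 alpha, by 5.70 ± 0.18, Il12b by 5.55 ± 0.13, the antisense transcript Il1bos by 5.52 ± 0.17, the siderophore-binding protein Lcn2 by 5.36 ± 0.16 and the early activation marker Cd69 by 5.24 ± 0.13. Decreases were smaller. The largest were those of Lfng, a glycosyltransferase acting on Notch (-3.20 ± 0.20), the cannabinoid receptor Cnr2 (-2.78 ± 0.18), Gpr146 (-2.65 ± 0.13), Gadd45g (-2.53 ± 0.28), the vitamin D receptor Vdr (-2.48 ± 0.14) and Cpt1a, which brings fatty acids into mitochondria (-2.42 ± 0.15). The adjusted p of these 13 genes ran from 4.13e-13 to 1.52e-05. MPI-2 mock means of Il12b, Il1bos, Lcn2 and Csf3 lay under background.

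NF-kB targets rose in 25 of 33 cases (28 adjusted over the list alone) with none lower (median 1.32, adjusted p = 5.75e-32). Ptgs2 rose by 4.16 ± 0.13, the inhibitor-family member Nfkbiz by 3.90 ± 0.16, Ccrl2 by 3.25 ± 0.14 and the ubiquitin-editing enzyme Tnfaip3 by 2.85 ± 0.12. Of 27 cytokines 20 rose (21 adjusted over the list alone) and none fell (median 1.44, adjusted p = 2.68e-26), with Csf3 higher by 4.47 ± 0.11 and Tnfsf15 by 4.76 ± 0.12. Of 25 chemokines 13 rose, the same adjusted over the list alone, and none fell (median 0.84, adjusted p = 3.86e-15). Cxcl10 rose by 4.92 ± 0.17, Ccl4 by 5.0 ± 0.20, Ccl22 by 3.10 ± 0.14 and Ccl20 by 3.43 ± 0.20. The lipid and PPAR list fell in 16 of 27 cases with 3 higher (18 and 4 adjusted over the list alone; median -0.70, adjusted p = 5.45e-07). The desaturase Scd1 fell, -2.10 ± 0.16, while the fatty acid-binding protein Fabp4 (1.53 ± 0.17), Dgat2 (1.0 ± 0.18) and Abca1 (0.41 ± 0.12) rose. Abca1 lost its call without any of the 6 MPI-2 arrays in turn, with values of 0.38 to 0.42. All 4 lists kept their call with an estimated correlation.

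Interferon genes did not pass camera as a group in MPI-2, while fry called the list higher (adjusted p = 0.000327). Of 46 members 13 rose, 8 fell (13 and 9 adjusted over the list alone) and 25 did not pass, and Ifnb1 itself was at 2.56 ± 0.21 in mock and 2.71 ± 0.11 in LPS, both under background (0.14 ± 0.24, adjusted p = 0.842). The median was -0.08, while the mean was 0.29 and camera pointed upward (adjusted p = 0.0968; adjusted p = 0.399 with an estimated correlation). Camera passed without MPI-2 mock replicate 2 (median -0.03, adjusted p = 0.03), with 13 members higher and 4 lower, and after cyclic loess (median -0.08, adjusted p = 0.0395), among genes above background (0.0264) and after quantile normalization (0.0441). The RNA sensor Ifih1 rose by 2.66 ± 0.14, Ifit1 by 2.25 ± 0.12, Ifi205 by 3.57 ± 0.25 and Ifi203 by 2.85 ± 0.23. Irgm1 fell, -1.06 ± 0.14, with Oas2, -0.85 ± 0.13, Oasl2, -0.69 ± 0.15, and Znfx1, -0.53 ± 0.12. Smaller decreases of Daxx (-0.55), Ddx58 (-0.43), Dhx58 (-0.59) and Usp18 (-0.46) lost their calls without single MPI-2 arrays. Without MPI-2 mock replicate 1 they were -0.45, -0.46, -0.43 and -0.51.

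Immediate early genes rose in 18 of 37 cases and fell in 6 (19 and 6 adjusted over the list alone; median 0.46, adjusted p = 7.23e-07; adjusted p = 0.482 with an estimated correlation). Dusp16 rose by 1.91 ± 0.14, Ier3 by 2.35 ± 0.18, the RNase Zc3h12a by 1.64 ± 0.15 and Btg2 by 1.57 ± 0.16. The transcription factors Fos (-1.03 ± 0.18), Fosb (-1.17 ± 0.17), Klf4 (-1.77 ± 0.23) and Myc (-0.80 ± 0.17) fell, as did Nr4a2 (-0.78 ± 0.21) and Egr2 (-0.41 ± 0.13). Egr2 lost its call without any 1 of the MPI-2 arrays (-0.34 to -0.45), and Nr4a2 without MPI-2 mock replicate 3 (-0.66), MPI-2 LPS replicate 1 (-0.71) or 3 (-0.77). Cell cycle genes fell in 27 of 54 cases with 1 higher (31 and 2 adjusted over the list alone; median -0.48, adjusted p = 3.89e-10; adjusted p = 0.059 with an estimated correlation). Cenpa fell, -1.14 ± 0.13, and the helicase subunit Mcm2, -0.97 ± 0.15, while Mad2l1 rose by 0.71 ± 0.12. Histone genes fell in 5 of 20 cases with none higher (10 adjusted over the list alone; median -0.46, adjusted p = 0.000474; adjusted p = 0.399 with an estimated correlation), among them H2ac4, -1.31 ± 0.20, and H4c8, -0.72 ± 0.16.

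Genes of antigen presentation rose in 7 of 27 cases and fell in 1 (11 and 2 adjusted over the list alone; median 0.21, adjusted p = 0.00171; adjusted p = 0.0572 with an estimated correlation). That list also holds genes that do not themselves present antigen, such as the chemokine Ccl17, higher by 2.08 ± 0.15, and the transcription factor Irf4, by 1.71 ± 0.16. Cd1d1 rose by 0.86 ± 0.155, and H2-DMa, a chaperone of peptide loading, fell, -1.33 ± 0.17. Scavenger receptors and lectins rose in 9 of 29 cases and fell in 1 (10 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.00171; adjusted p = 0.274 with an estimated correlation). Clec4a1 rose by 1.96 ± 0.16 and Clec4d by 1.26 ± 0.17, and Scarb1 fell, -1.38 ± 0.23. The neutrophil list had 4 of 16 members higher and 1 lower, the same adjusted over the list alone (median 0.14, adjusted p = 0.00228; adjusted p = 0.138 with an estimated correlation). Besides Lcn2 they included S100a8 (1.77 ± 0.17) and the collagenase Mmp8 (1.53 ± 0.19), and the chemokine receptor Cxcr2 fell, -1.37 ± 0.15.

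Tnf rose in MPI-2 by 2.14 ± 0.14, Il1b by 1.75 ± 0.17, Cd14, the co-receptor for LPS, by 2.64 ± 0.13 and Marco by 0.94 ± 0.16, while Pparg fell, -0.71 ± 0.14. Il1a rose by 1.12 ± 0.29 from a mock level of 10.8 ± 0.17 (SD, n = 3), about 2 below the highest value of the table, 12.82, and lost its call without MPI-2 mock replicate 1 (1.03) or MPI-2 LPS replicate 3 (1.01). Csf1r fell, -0.45 ± 0.14, a call lost without any 1 of the MPI-2 arrays (-0.40 to -0.51). Il10 (0.13 ± 0.25, adjusted p = 0.856), Nos2 (0.11 ± 0.15, adjusted p = 0.794), Tlr4 (-0.27 ± 0.19, adjusted p = 0.484) and Csf2rb (-0.14 ± 0.14, adjusted p = 0.672) did not pass, with Il10 and Nos2 under background in both MPI-2 groups. In all, 1031 genes rose and 1910 fell, 368 and 455 of them at least 2-fold, and 4694 had an unadjusted p under 0.05. The count was 2106 to 2463 with any MPI-2 array left out, and 1612 with the replicate numbers of the sample descriptions as a block. Fitted on the 6 arrays of each cell type alone it was 5026 in MPI-2 and 3464 in BMM, so which cell type has more changed genes depends on the arrays in the fit. The main fit shares 1 residual spread per gene, while the median gene SD was 0.176 and 0.204 in BMM mock and LPS against 0.12 and 0.109 in MPI-2. The 2 counts of the main fit therefore do not show which cell type changed more genes. The list of M-CSF-grown macrophages (4 higher, 13 lower of 40; median 0.01, adjusted p = 0.0928) passed after quantile normalization (-0.05, 0.0498).

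**Figure D2:**
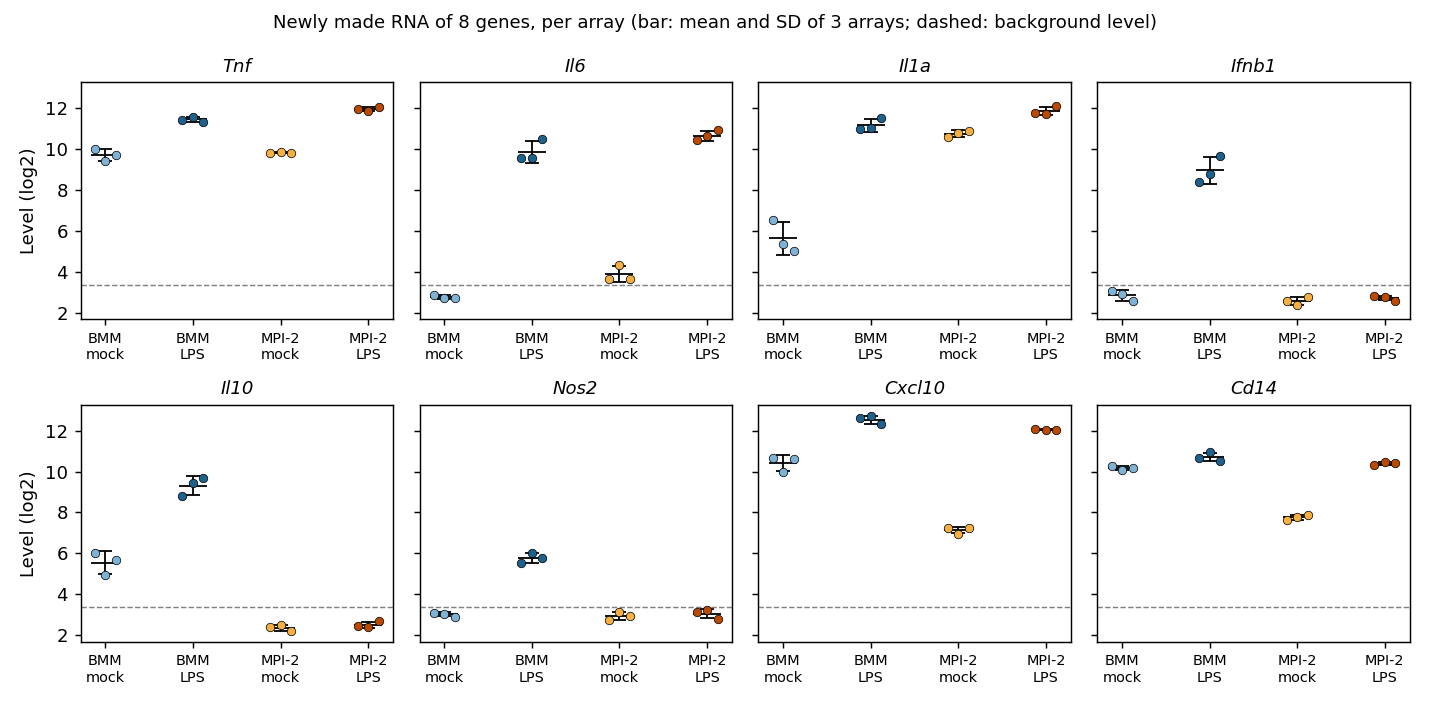
Log2 expression of Tnf, Il6, Il1a, Ifnb1, Il10, Nos2, Cxcl10 and Cd14 on each array (dots) by group, with the mean and SD of 3 arrays as bars and the background level as a dashed line. Il6 reaches 9.87 in BMM LPS and 10.7 in MPI-2 LPS, and Ifnb1 reaches 8.96 in BMM LPS and 2.71 in MPI-2 LPS.

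Whether the 2 kinds of macrophage answered LPS differently was tested as the MPI-2 change minus the BMM change. The interferon genes differed most. None of the 46 had a higher response in MPI-2 and 40 had a lower one (43 adjusted over the list alone; median log2 -2.40, adjusted p = 1.75e-51; adjusted p = 5.12e-05 with an estimated correlation). The difference was -4.85 ± 0.20 (SE) for Mx2, -4.73 ± 0.23 for Cmpk2, -4.66 ± 0.20 for Gbp5 and -4.45 ± 0.23 for Mx1. Large negative differences of single genes included Ch25h (-6.17 ± 0.21) and Ifnb1 (-5.97 ± 0.35), the T cell co-stimulator Tnfsf4 (-5.0 ± 0.23) and Cxcl11 (-4.97 ± 0.20). In MPI-2 these 4 and Mx2 and Mx1 were under background in both groups, so their changes there could not be measured and the size and order of these differences are not exact.

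Other genes had the higher response in MPI-2. The largest differences were those of Il1bos (5.17 ± 0.24), Il1f6 (5.02 ± 0.26), Arrdc3 (4.14 ± 0.21), granulocyte colony-stimulating factor (Csf3, 4.13 ± 0.16), the growth factor Ereg (4.12 ± 0.19) and hepatocyte growth factor (Hgf, 3.93 ± 0.44). Il1bos and Csf3 lay under background in MPI-2 mock, so the size and order of these differences are not exact. Il1bos overlaps Il1b on the opposite strand, and which strand its probes read was not tested here. The difference of Arrdc3 was that between a decrease in BMM (-4.39) and -0.25 in MPI-2 (adjusted p = 0.355). Hgf fell in BMM as well (-3.67 ± 0.31), so its difference too came mostly from a decrease in BMM. Cxcl10 (2.79 ± 0.24) and Cd14 (2.11 ± 0.18) rose more in MPI-2, from lower mock levels there, and neither was higher in MPI-2 than in BMM after LPS. Csf2rb (1.21 ± 0.19) and Csf1r (0.77 ± 0.20) fell in BMM, and the fall in MPI-2 was smaller for Csf1r and did not pass for Csf2rb. Marco differed by 0.76 ± 0.23, a call lost without 8 of the 12 arrays in turn (0.59 to 0.79). Il1a (-4.43 ± 0.40), Il10 (-3.64 ± 0.35) and Nos2 (-2.65 ± 0.22) had the lower response in MPI-2, the last 2 under background in both MPI-2 groups. Il1a started from a higher mock level in MPI-2 and was not lower there after LPS. Responses of Il6 (-0.32 ± 0.34, adjusted p = 0.691), Tnf (0.40 ± 0.20, 0.256), Il1b (-0.69 ± 0.24, 0.0823), Tlr4 (0.12 ± 0.27, 0.871) and Pparg (0.34 ± 0.20, 0.357) were not shown to differ, though Il1b passed without BMM mock replicate 1 (-0.88).

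Among NF-kB targets 8 had a higher and 7 a lower response in MPI-2 (9 and 11 adjusted over the list alone; median -0.33, adjusted p = 0.607), with Cd40 at -4.28 ± 0.22 and Nfkbiz at 2.40 ± 0.22. Immediate early genes had a higher response in 13 of 37 cases and a lower one in 7 (15 and 8 adjusted over the list alone; median 0.53, adjusted p = 0.0114; adjusted p = 0.822 with an estimated correlation). Btg2 differed by 3.19 ± 0.22, Nr4a1 by 3.73 ± 0.38 and Ier3 by 2.35 ± 0.26, against Egr2 (-2.36 ± 0.18), Dusp2 (-2.12 ± 0.29), Maff (-1.16 ± 0.25), Fosl1 (-1.14 ± 0.26), Csrnp1 (-1.10 ± 0.23), Socs3 (-1.17 ± 0.32) and Mafk (-0.95 ± 0.28). The last 2 lost their calls without at least 8 of the arrays in turn (-0.99 to -1.16 and -0.80 to -0.99). The list lost its call without BMM mock replicate 1 (median 0.39) or BMM LPS replicate 3 (median 0.24) and was at 0.20 without both (adjusted p = 0.254), and among genes above background it did not pass (adjusted p = 0.0623). Histone genes had the higher response in MPI-2 in 7 of 20 cases and the lower in 1 (8 and 1 adjusted over the list alone; median 0.45, adjusted p = 0.0114; adjusted p = 0.822 with an estimated correlation). H1f2 differed by 3.34 ± 0.23 and H2bc4 by 3.11 ± 0.44, against H2ac4 at -1.30 ± 0.29, and without BMM mock replicate 1 the list's median was 0.19 (adjusted p = 0.104). Polarisation genes had the lower response in 8 of 18 cases and the higher in 3, the same adjusted over the list alone (median -0.42, adjusted p = 0.0165; adjusted p = 0.822 with an estimated correlation). Chil3 (-1.81 ± 0.19) and Cd274 (-2.41 ± 0.26) were among them, against Acod1 (1.45 ± 0.18), Tgm2 (1.38 ± 0.23) and Gpr18 (1.07 ± 0.22), and without BMM LPS replicate 2 that list was at -0.32 (adjusted p = 0.0847).

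Responses were also shared. Of 6295 genes called in either cell type 1760 were called in both, and 1552 of these (88.2%) changed in the same direction, 516 upward and 1036 downward. Independent lists of these sizes would share 106.2 upward and 293.2 downward, and the 139 and 69 genes that moved in opposite directions stand beside 196.7 and 158.3. Over all genes, which are not independent replicates, the changes correlated at r = 0.465 (rho = 0.382), and each response had its own mock arrays. In the difference itself 1412 genes were higher in MPI-2 and 1250 lower, 756 and 742 of them by at least 2-fold, and 4548 had an unadjusted p under 0.05. That majority turned under other scalings, with 1200 higher and 1574 lower after cyclic loess, 1178 and 1331 with arrays shifted to a common median and 1280 and 1402 after quantile normalization. The cytokine list, with a median of -0.69 (6 higher, 13 lower; 7 and 14 adjusted over the list alone; adjusted p = 0.0675), passed without BMM mock replicate 1 (-0.79), BMM LPS replicate 1 (-0.78) or MPI-2 LPS replicate 3 (-0.78), after quantile normalization (-0.80, adjusted p = 0.0464) and without BMM mock replicate 1 and BMM LPS replicate 3 together (-0.80, 0.0362), when the chemokine list passed too (-0.51, 0.0362). The sensing list (3 higher, 8 lower of 31; median -0.28, adjusted p = 0.0675) passed after cyclic loess (-0.36, 0.0219) and without BMM mock replicate 3 (-0.28, 0.0294), BMM LPS replicate 1 (-0.29, 0.0275) or MPI-2 LPS replicate 3 (-0.29, 0.0396). The list of M-CSF-grown macrophages (14 higher, 8 lower of 40; 0.34, 0.167) passed without BMM mock replicate 2 (0.50, 0.0477).

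**Figure D3:**
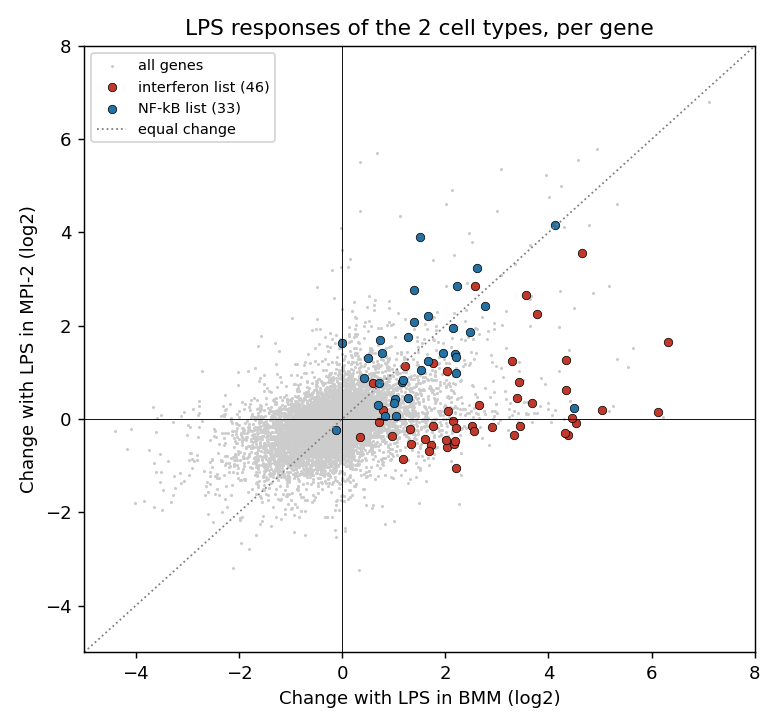
Log2 change after LPS in BMM (x) and in MPI-2 (y), with each point a gene, the 46 interferon genes in red, the 33 NF-kB targets in blue and equal change as a dotted line. The interferon genes have a median of 2.37 in BMM and -0.08 in MPI-2, and the NF-kB targets 1.39 and 1.32.

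MPI-2 and BMM were next compared without LPS. Carbonic anhydrase 4 (Car4), a gene of alveolar macrophages, was higher in MPI-2 by log2 6.93 ± 0.13 (SE), at 10.3 ± 0.032 against 3.39 ± 0.28 (SD, n = 3). Cyclin D2 (Ccnd2, 6.46 ± 0.14), the activin subunit Inhba (6.29 ± 0.22), Plet1 (6.16 ± 0.39) and the cytokine-signalling inhibitor Socs2 (5.49 ± 0.16) followed. The antiviral membrane protein Ifitm3 was lower in MPI-2, -7.51 ± 0.20, with the complement gene C1qb, -7.01 ± 0.18, Cxcl16, -6.92 ± 0.16, Ms4a7, -6.84 ± 0.13, and the sphingosine phosphate receptor S1pr1, -6.42 ± 0.20. These 5 lay under background in MPI-2 mock. A further probe set of Socs2 gave 1.93.

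Every measured cell cycle gene, 54 of 54, was higher in MPI-2, the same adjusted over the list alone (median 2.21, adjusted p = 1.58e-37). Bub1b was higher by 3.51 ± 0.12, Kif20a by 3.47 ± 0.12 and the proliferation marker Mki67 by 3.48 ± 0.13. Of 20 genes of cholesterol synthesis 17 were higher and none lower, the same adjusted over the list alone (median 2.46, adjusted p = 2.24e-13), with Sqle at 3.90 ± 0.15, Stard4 at 3.28 ± 0.15 and Cyp51 at 3.89 ± 0.18. Of 37 alveolar macrophage genes 31 were higher and 3 lower, again the same adjusted over the list alone (median 2.29, adjusted p = 6.9e-19). Slc7a2 was at 5.42 ± 0.13, Chil3 at 4.92 ± 0.14 and Ly75 at 4.31 ± 0.13, against Cd36 at -3.34 ± 0.23, Tgfbr1 at -0.52 ± 0.12 and Siglecf at -0.56 ± 0.16. Siglecf lost its call without BMM mock replicate 2 (-0.47) or MPI-2 mock replicate 2 (-0.51). The lipid and PPAR list had 18 of 27 higher and 5 lower, the same adjusted over the list alone (median 1.25, adjusted p = 1.54e-05). Scd1 was at 4.91 ± 0.16 and Mgll at 4.28 ± 0.18, both under background in BMM mock as Chil3 and Ly75 were, with Dgat2 at 4.12 ± 0.18, against Pltp (-5.01 ± 0.20), Abca1 (-0.57 ± 0.12), Mylip (-1.67 ± 0.12), Lipa (-0.73 ± 0.13) and the scavenger receptor Cd36.

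Interferon genes were lower in MPI-2 before LPS as well, 37 of 46 with none higher, the same adjusted over the list alone (median -1.82, adjusted p = 3.06e-20), with Ifit3 at -5.62 ± 0.15, Ifit1 at -3.70 ± 0.12 and Rtp4 at -3.48 ± 0.13. Of 40 genes of M-CSF-grown macrophages 27 were lower and 6 higher (28 and 6 adjusted over the list alone; median -1.17, adjusted p = 2.35e-09). C1qc was at -5.71 ± 0.20 and Lgmn at -5.37 ± 0.18, against Axl (2.76 ± 0.14), Slco2b1 (1.91 ± 0.16), Mertk (1.95 ± 0.22), Cd300lf (3.46 ± 0.18), P2ry12 (0.73 ± 0.13, under background in all groups) and Sirpa (0.43 ± 0.14). Sirpa lost its call without BMM mock replicate 2 (0.33) or any MPI-2 mock array (0.40 to 0.44). These 6 lists kept their call with an estimated correlation. Ribosomal protein genes were higher in 23 of 34 cases and lower in none, the same adjusted over the list alone (median 0.90, adjusted p = 4.52e-08; adjusted p = 0.139 with an estimated correlation), with Rps20 at 2.15 ± 0.14 and Rplp0 at 2.22 ± 0.17. Chemokines were lower in 12 of 25 cases and higher in 5 (14 and 5 adjusted over the list alone; median -0.43, adjusted p = 0.00339; adjusted p = 0.449 with an estimated correlation). The monocyte attractants Ccl2 (-4.06 ± 0.17) and Ccl7 (-3.96 ± 0.20) were lower, against Ccl17 (4.82 ± 0.15), Ccl22 (1.18 ± 0.14), Cx3cl1 (1.05 ± 0.28), Ccl6 (3.66 ± 0.19) and Ccl3 (0.47 ± 0.14). Ccl3 lost its call without BMM mock replicate 2 (0.34) or MPI-2 mock replicate 3 (0.41).

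Il1a was higher in MPI-2 by 5.13 ± 0.29, Il1b by 1.08 ± 0.17, Il6 by 1.11 ± 0.24, Pparg by 2.24 ± 0.14, Marco by 2.23 ± 0.16, Tlr4 by 1.90 ± 0.19 and Csf2rb by 1.28 ± 0.14. Cxcl10 was lower, -3.27 ± 0.17, with Il10, -3.19 ± 0.25, Cd14, -2.43 ± 0.13, and Csf1r, -0.95 ± 0.14. Tnf (0.11 ± 0.14, adjusted p = 0.564), Ifnb1 (-0.28 ± 0.24, 0.391) and Nos2 (-0.07 ± 0.15, 0.738) did not pass, the last 2 being under background in both. In all, 4108 genes were higher in MPI-2 and 3579 lower, 2053 and 1010 of them at least 2-fold. The median of all genes was log2 -0.10, so relative to it every difference stands higher by that much, and with arrays shifted to a common median 4799 were higher and 2084 lower (69.7% higher in place of 53.4%). The shift used all probe sets and left the median of the tested genes at 0.0468. Values also spread more widely in MPI-2 mock (mean interquartile range over genes 3.40 against 2.86 in BMM mock). After cyclic loess 3562 were higher and 3080 lower, with 76% of the calls kept. Lists of histones (13 higher, 3 lower of 20; adjusted p = 0.00716, and 0.47 with an estimated correlation), glycolysis (12 and 5 of 26; 0.0316 and 0.504), NF-kB targets (6 and 17 of 33; 0.0316 and 0.504) and Toll-like receptor sensing (9 and 17 of 31; 0.0425 and 0.47) passed camera alone. Without BMM mock replicate 3 the NF-kB (median -0.46, adjusted p = 0.0535) and sensing lists (-0.41, 0.0993) no longer passed, and without MPI-2 mock replicate 1 neither did glycolysis (0.37, 0.0589). The glycolysis call was also lost after cyclic loess (median 0.26, adjusted p = 0.431), the median shift (0.64, 0.0712) and quantile normalization (0.31, 0.205) and among genes above background (0.49, 0.303), where that of histones was lost too (0.89, 0.177). The immediate early list, not past at an adjusted p of 0.124, passed after cyclic loess (-0.64, 0.000378), the median shift (-0.13, 0.0255) and quantile normalization (-0.50, 0.00297), among genes above background (-0.28, 0.0239) and without BMM mock replicate 2 (-0.36, 0.0489). The sensing list was also lost without MPI-2 mock replicate 3 (0.0542), BMM LPS replicate 2 (0.0638) or BMM LPS replicate 3 (0.0517).

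The same comparison after LPS gave wider gaps in the interferon genes. Ifitm3 was lower in MPI-2, log2 -8.40 ± 0.20 (SE), with Ifit3, -7.96 ± 0.15, Mx2, -7.71 ± 0.14, and Cmpk2, -7.58 ± 0.17, each under background in MPI-2 LPS. Of the 46 interferon genes 45 were lower and 1 higher, the same adjusted over the list alone (median -4.24, adjusted p = 4.04e-37). The exception, Slfn2, was at 0.43 ± 0.12 and lost its call without MPI-2 LPS replicate 2 (0.37). Car4 was higher in MPI-2 by 7.90 ± 0.13, Plet1 by 7.07 ± 0.39, the activin antagonist Fst by 6.66 ± 0.17, the lectin Clec4n by 6.08 ± 0.11, the protease Ctsk by 6.00 ± 0.16 and Ccl17 by 5.99 ± 0.15.

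Of 54 cell cycle genes 52 were higher and none lower, the same adjusted over the list alone (median 2.27, adjusted p = 3.43e-33), with Ccna2 at 3.83 ± 0.12. Cholesterol synthesis genes were higher in 17 of 20 cases and lower in none, the same adjusted over the list alone (median 2.20, adjusted p = 1.62e-11). Alveolar macrophage genes were higher in 27 of 37 cases and lower in 4 (28 and 4 adjusted over the list alone; median 2.45, adjusted p = 9.06e-13). The 4 were Cd36 (-3.77 ± 0.23), Tgfbr1 (-0.51 ± 0.12), Siglecf (-0.54 ± 0.16) and Cd2 (-0.45 ± 0.15, under background in all groups). Siglecf and Cd2 lost their calls without BMM LPS replicate 3 (-0.42 and -0.29) or MPI-2 LPS replicate 3 (-0.48 and -0.37), Siglecf also without BMM LPS replicate 1 (-0.44) and Cd2 without MPI-2 LPS replicate 1 (-0.45). The lipid and PPAR list had 18 of 27 higher and 4 lower, the same adjusted over the list alone (median 1.30, adjusted p = 1.25e-05). These 4 lists and the interferon list kept their call with an estimated correlation. Genes of M-CSF-grown macrophages were lower in 25 of 40 cases and higher in 5 (27 and 5 adjusted over the list alone; median -1.22, adjusted p = 5.84e-08; adjusted p = 0.057 with an estimated correlation), Ms4a7 at -6.45 ± 0.13 and Vcam1 at -4.59 ± 0.15 among them.

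Il10 was lower in MPI-2 LPS, -6.82 ± 0.25, with Ifnb1, -6.25 ± 0.24, and Nos2, -2.73 ± 0.15, while Marco was higher by 2.98 ± 0.16, Pparg by 2.58 ± 0.14, Csf2rb by 2.49 ± 0.14, Tlr4 by 2.02 ± 0.19 and Tnf by 0.52 ± 0.14. Il6 was higher by 0.80 ± 0.24 and Cxcl10 lower, -0.49 ± 0.17. Il6 lost its call without BMM LPS replicate 1 or 2 (0.64 in both) or MPI-2 LPS replicate 3 (0.67), and Cxcl10 without any 1 of 5 arrays (-0.41 to -0.49). Il1a (0.70 ± 0.29, adjusted p = 0.0573), Il1b (0.39 ± 0.17, 0.0774), Cd14 (-0.32 ± 0.13, 0.0559) and Csf1r (-0.18 ± 0.14, 0.291) did not pass, though without BMM LPS replicate 3 Il1a (0.89), Il1b (0.48) and Cd14 (-0.41) did. In all, 4488 genes were higher and 4312 lower, 2431 and 1057 of them at least 2-fold. The median of all genes was -0.14, and with arrays shifted to a common median 4901 were higher and 2676 lower (64.7% higher in place of 51%). The mean interquartile range over genes was 3.18 in MPI-2 LPS against 2.51 in BMM LPS. After cyclic loess 3601 were higher and 3554 lower, with 68.8% of the calls kept. Lists of ribosomal proteins (24 higher, 1 lower of 34; adjusted p = 6.14e-09, and 0.109 with an estimated correlation), histones (15 and 0 of 20; 1.66e-07 and 0.169), chemokines (6 and 16 of 25; 0.00194 and 0.308), sensing (9 and 18 of 31; 0.00578 and 0.25), NF-kB targets (7 and 20 of 33; 0.00666 and 0.389) and housekeeping genes (8 and 2 of 13; 0.0225 and 0.308) passed camera alone. The housekeeping call was lost after cyclic loess (median 0.16 in place of 0.55, adjusted p = 0.471) and quantile normalization (0.18, 0.119) and among genes above background (0.55, 0.246). The antigen presentation list (9 and 5 of 27; 0.14, 0.086) passed after cyclic loess (0.23, 0.032) and quantile normalization (0.17, 0.043), and glycolysis (12 and 4 of 26; 0.38, 0.086) without BMM LPS replicate 2 (0.51, 0.0341).

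**Figure D4:**
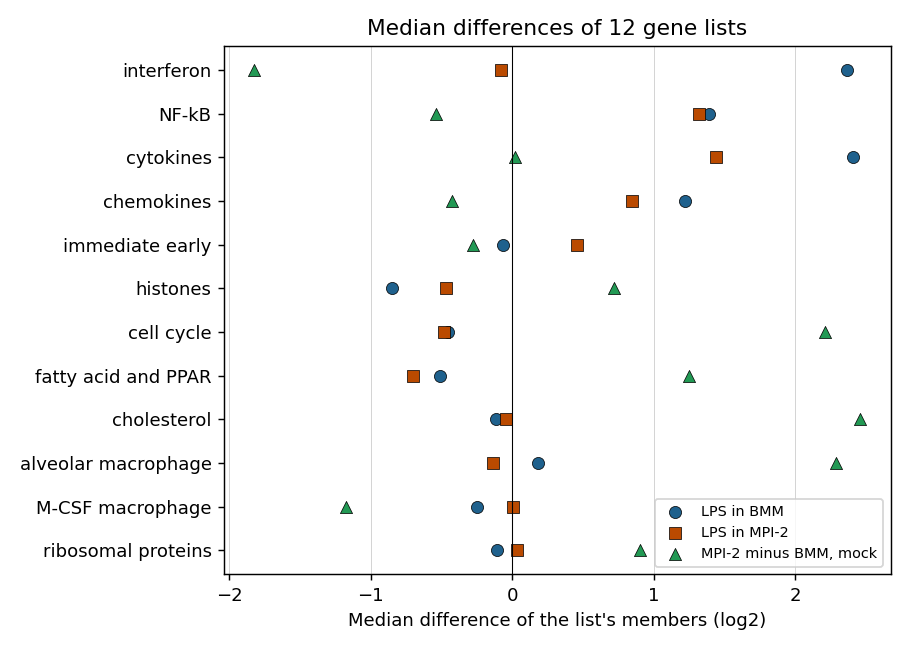
Median log2 difference of 12 gene lists for LPS in BMM, LPS in MPI-2 and MPI-2 minus BMM in mock. The interferon list is at 2.37, -0.08 and -1.82, and the cell cycle list at -0.45, -0.48 and 2.21.

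Markers of other cell types were mostly at background. The lists for hepatocytes, B cells, T and NK cells, mast cells, stromal cells, erythroid cells and progenitors passed camera in none of the 5 comparisons, and the neutrophil list passed in MPI-2 after LPS, a call lost with an estimated correlation (adjusted p = 0.138). At an unadjusted camera p under 0.05 the B cell list (0.0432) was lower in MPI-2 mock and the neutrophil list (0.0169) higher in the difference of responses. Past adjustment the latter missed the threshold (3 higher, 1 lower of 16; median 0.14, adjusted p = 0.0675), but it passed after cyclic loess (0.18, 0.0219) and quantile normalization (0.16, 0.0464), among genes above background (0.56, 0.0257) and without BMM LPS replicate 1 (0.18, 0.0315). Fry called some of the lists for other cell types, among them that of B cells as lower in MPI-2 mock (adjusted p = 9.11e-06). The transferrin gene Trf fell in BMM, -2.93 ± 0.17, the carbonic anhydrase Car2 rose in MPI-2, 2.55 ± 0.21, and the B cell adaptor Blnk was lower in MPI-2 mock, -4.90 ± 0.15.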

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

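The tests in the 3 patterns weighed first, on LPS sensing, normalization, background, Ifnb1, signal compression and signal level, were chosen only after the results were seen, while the counts over other splits of the arrays were planned. The results given after them are those whose LPS response differed between BMM and MPI-2 by the test of the difference itself.

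Interferon genes rose after LPS in BMM, with a list median of log2 2.37, and were at -0.08 in MPI-2, a difference of -2.40. Failure of MPI-2 to receive or sense LPS is argued against by the NF-kB targets, whose median change in MPI-2 was 0.953 of that in BMM (0.848 to 1.05 with single arrays left out). Without BMM mock replicate 1 and BMM LPS replicate 3 together the medians were 1.32 in MPI-2 and 1.75 in BMM, so weaker sensing stays open. The list still rose in MPI-2 in that fit, with 27 members higher and none lower. Normalization is argued against as well, since 42 of the 46 members still had the lower response in MPI-2 after cyclic loess, and so are responses hidden under background as the whole account, since 28 of the 34 members above it in both MPI-2 groups had the lower response. An induction of Ifnb1 in MPI-2 to the level of BMM is argued against, since it rose by 6.12 in BMM and stayed under background in MPI-2 LPS. Whether a smaller induction occurs in MPI-2, with only the feedback through the interferon receptor missing, stays open. The change of Ifnb1 there, 0.142, was measured under background in both groups (2.56 and 2.71). A hypothesis is that MPI-2 cells may sense LPS and yet transcribe fewer interferon genes by 90 min, which later time points and a more sensitive assay of Ifnb1 would test; differences of origin, growth factor and medium stay open, and 13 members rose in MPI-2 all the same.

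In BMM 3061 genes fell and 2053 rose after LPS, and the LPS arrays had a narrower spread of values than the mock arrays, with a mean interquartile range over genes of 2.51 against 2.86 in BMM and 3.18 against 3.40 in MPI-2. After cyclic loess 49.8% of the called genes rose in BMM, against 40.1% in the deposited values. Cyclic loess need not even the balance (39.3% rose in MPI-2 after it, against 35.1%), but it takes out a trend with signal level whether technical or real, so compression of the signal on the BMM LPS arrays and a real excess of decreases cannot be told apart. Compression alone is argued against for most of the falling genes taken singly, since 2339 of the 3061 (76.4%) still fell after cyclic loess.

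Cell cycle genes had a median of log2 -0.45 after LPS in BMM and -0.48 in MPI-2, with 17 of 54 lower in both, calls lost in both with an estimated correlation (adjusted p = 0.134 and 0.059). A general decrease of genes at that signal level stays open. The medians lay at the 0.42 and 0 percentiles of 10000 lists matched on mean level over all arrays. That level lies between those of the cell types, since the list was higher in MPI-2 mock by a median of 2.21. Such lists also leave out the correlation between cell cycle genes, and both camera calls were lost where it was estimated from the data. Normalization between arrays stays open for BMM, where 15 members fell after cyclic loess in place of 27, and in MPI-2 25 did. LPS may lower transcription of cell cycle genes in both kinds of macrophage within 90 min, but no test here decides it, and counts of dividing cells in the same cultures would be needed.

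The 2662 genes whose response differed were set against 100 drawn splits, of 200 distinct ones, that exchange mock and LPS within each cell type. Among those drawn only the real split reached that count (1 of 100, with 2458 as the highest other). Such splits also break up the LPS response within each cell type. The count therefore cannot decide whether equal responses in both cell types would call as many genes. The split that turns mock and LPS round in a single cell type was not among those drawn and calls more, 5531 genes. That split tests the sum of both responses, so a high count need not mean that the responses differ. For the other comparisons 10 splits of 6 arrays are too few for a share under 0.05. The real counts and the highest others were 5114 and 7 for LPS in BMM, 2941 and 0 for LPS in MPI-2, 7687 and 0 for mock and 8800 and 0 for LPS between cell types, the real split being the 1 highest in each. Every other split mixes arrays of both real groups on each side, so a real difference adds to the spread within its groups. Low counts of the other splits follow from that, and the size of the gap says little.

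Besides the interferon list, camera passed for immediate early genes (median difference of response 0.527), histones (0.454) and polarisation genes (-0.421), and each of these calls was lost with an estimated correlation (adjusted p = 0.822). The immediate early median was 0.203 without BMM mock replicate 1 and BMM LPS replicate 3 together, the histone median 0.188 without BMM mock replicate 1 and the polarisation median -0.323 without BMM LPS replicate 2. The values that follow are log2 differences of response, MPI-2 minus BMM, each past limma's adjusted threshold, and not exact where a cell type lay under background, for the genes named in this text, which are part of the members that differed. A higher response can be a smaller decrease, as for Csf1r, and need not mean a higher level after LPS, as for Cxcl10 and Cd14. Likewise Il1a, with the lower response, was not lower in MPI-2 after LPS. Without MPI-2 mock replicate 1 the calls of Ccrl2 (0.53), Cd28 (1.42), Cnr2 (-0.86), Gpr146 (-0.68), Ifitm3 (-0.86), Irf4 (-0.73), Lfng (-1.02), Lif (-0.85), Mafk (-0.94), Marco (0.70), Pgk1 (-0.54), Rps20 (-0.59), Socs3 (-1.16) and Tnfaip3 (0.63) were lost, in part also without other arrays. Inhba lost its call without BMM mock replicate 2 (-0.76) and 7 other arrays in turn, and P2ry12 without MPI-2 mock replicate 2 (-0.49) and 7 others, and P2ry12 lay under background in all groups.

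Interferon genes with the lower response in MPI-2 included Ifnb1 at -5.97, Mx2 at -4.85, Cmpk2 at -4.73, Gbp5 at -4.66, Mx1 at -4.45, Irgm1 at -3.26, Gbp3 at -3.07, Usp18 at -2.65 and Dhx58 at -2.62. Smaller gaps included those of Oasl2 at -2.38, Ifit3 at -2.35, Daxx at -2.27, Ddx58 at -2.04, Oas2 at -2.04, Znfx1 at -1.86, Ifit1 at -1.53, Ifih1 at -0.91 and Rtp4 at -0.78. Cytokine genes with the lower response in MPI-2 included Il1a at -4.43, Il10 at -3.64, Il27 at -3.20, Il15 at -2.61, Inhba at -1.07 and Lif at -0.82. Those with the higher one included Il1f6 at 5.02, Csf3 at 4.13, Osm at 3.35, Il12b at 0.98 and Tnfsf15 at 0.75. Chemokine genes with the lower response in MPI-2 included Cxcl11 at -4.97, Cxcl9 at -4.04, Ccl7 at -3.17 and Ccl5 at -2.17. Against these, the higher ones included Ccl20 at 3.29, Cxcl10 at 2.79, Ccl17 at 1.16 and Cxcl16 at 1.01. Genes of NF-kB feedback and microbial sensing with the lower response in MPI-2 included Cd40 at -4.28, Tlr1 at -1.77 and Ikbke at -1.26. The other direction included Tlr13 at 3.14, Nfkbiz at 2.40, Cd14 at 2.11, Tlr9 at 1.16, Ccrl2 at 0.62 and Tnfaip3 at 0.61. Immediate early genes with the lower response in MPI-2 included Egr2 at -2.36, Dusp2 at -2.12, Socs3 at -1.17, Maff at -1.16, Fosl1 at -1.14, Csrnp1 at -1.10 and Mafk at -0.95. Those with the higher one included Nr4a1 at 3.73, Btg2 at 3.19, Ier3 at 2.35, Zc3h12a at 1.33, Nr4a2 at 1.29 and Fos at 1.17.

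Histone and cell cycle genes with the lower response in MPI-2 included E2f8 at -2.00, Mki67 at -1.64 and H2ac4 at -1.30. Against these, the higher ones included H1f2 at 3.34, H2bc4 at 3.11, H2bc8 at 2.12, H3c4 at 1.98, Cenpa at 1.42, Ccna2 at 0.92 and Mcm7 at 0.64. Genes of lipid metabolism and glycolysis with the lower response in MPI-2 included Scd1 at -1.80, Pfkfb3 at -1.58, Cpt1a at -1.48, Mgll at -1.39, Lpcat3 at -1.07 and Pgk1 at -0.56. The other direction included Vegfa at 2.79, Lipa at 2.32, Egln3 at 1.85, Dgat2 at 1.58, Scd2 at 1.54, Abca1 at 0.89, Ldha at 0.79 and Mylip at 0.76. Macrophage and polarisation genes with the lower response in MPI-2 included Vcam1 at -4.29, Fcgr4 at -4.10, Axl at -3.09, Slc7a2 at -2.97, Nos2 at -2.65, Cd274 at -2.41, Slco2b1 at -1.91, Chil3 at -1.81, Folr2 at -1.68 and P2ry12 at -0.60. Those with the higher one included Stab1 at 2.42, Lgmn at 2.05, Acod1 at 1.45, Tgm2 at 1.38, Ctsk at 1.28, Fabp4 at 1.25, Mertk at 1.21, Gpr18 at 1.07, Car4 at 0.97, Csf1r at 0.77 and Marco at 0.76. Genes of colony-stimulating factor signalling, transcription control, antigen presentation and uptake with the lower response in MPI-2 included Ccnd2 at -3.39, Tfec at -3.27, Cish at -2.92, Stat5a at -1.79, Csf3r at -1.66, H2-DMa at -1.22, Socs2 at -0.96, Jak2 at -0.94 and Irf4 at -0.82. Against these, the higher ones included Cebpa at 1.64, Mef2c at 1.32, Clec4d at 1.25, Csf2rb at 1.21, Clec4a1 at 1.2 and Clec4n at 0.99. Ribosomal protein genes, housekeeping genes and markers of other cell types with the lower response in MPI-2 included Cxcr2 at -1.30 and Rps20 at -0.69. The other direction included Lcn2 at 2.27, Trf at 2.20, Gusb at 2.03, Car2 at 1.91, S100a8 at 1.65, Mmp8 at 1.57, Cd28 at 1.57 and Blnk at 0.90.

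Genes of no list with the lower response in MPI-2 included Ch25h at -6.17, Tnfsf4 at -5.0, Gadd45g at -2.40, Vdr at -1.76, Lfng at -1.09, Cnr2 at -0.98, Ifitm3 at -0.89 and Gpr146 at -0.70. Those with the higher one included Il1bos at 5.17, Arrdc3 at 4.14, Ereg at 4.12, Hgf at 3.93, Lhfpl2 at 3.86 and Lpar6 at 3.53. Smaller gaps included those of Slc43a2 at 2.23, S1pr1 at 2.12, Cytip at 2.08, Fst at 1.74, Cd69 at 1.29 and Mmp13 at 0.83.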

How the results depend on the processing

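The alternatives chosen after seeing the data were the joint removal of BMM mock replicate 1 and BMM LPS replicate 3, quantile normalization of the probe sets, the median shift for the agreement of responses and, for the gene lists, leaving out single arrays. Of 17175 checks of named genes 16549 kept the call and its direction or had no call in either fit. Of the others 448 lost the call, 176 gained it and 2 reversed. Direction was not compared where neither fit gave a call. Of 2630 checks of gene lists 2538 stayed the same in that sense, 59 lost the call and 33 gained it. Counted by gene, every alternative kept the call of 145 of 157 called named genes for LPS in BMM and 99 of 129 in MPI-2. Those for the difference were 131 of 149, for mock 158 of 169 and for LPS between cell types 159 of 175. No gene called in the deposited values turned direction among the calls under cyclic loess, a shift to a common median or quantile normalization. Under cyclic loess 82.3% of the calls remained for LPS in BMM and 68.8% for LPS between cell types. Plet1 in BMM, not called at -0.19, was 0.65 without BMM mock replicate 1 and BMM LPS replicate 3 together, and Abca1 between cell types in LPS, 0.32, was -0.047 after cyclic loess; the cause was not tested. A log2 size of at least 1 left 1823 genes for LPS in BMM, 823 in MPI-2, 1498 for the difference of responses, 3063 for mock and 3488 for LPS between cell types, fewer by construction, as did an adjusted p under 0.01 with 1955 in MPI-2 and 1600 for the difference. The 2941 genes of MPI-2 became 5026 with its 6 arrays alone and 5183 with array weights, while the 5114 of BMM became 3464 and 4477, so that the order of the cell types turned. With the 6 arrays alone the log2 changes stay the same, and only the residual spread and its degrees of freedom differ. The median gene SD was 0.176 and 0.204 in BMM mock and LPS against 0.12 and 0.109 in MPI-2. The cause of the shift with array weights was not tested. The labels do not say whether replicate numbers pair the samples. Arrays with the same title number deviated together at r of 0.242, -0.09 and -0.01 in BMM and 0.05, -0.15 and -0.09 in MPI-2. With the description numbers r was -0.025 and 0.113 in MPI-2. These values show little shared deviation and do not decide the pairing. With the title numbers as a replicate block the counts were 5070, 2953, 2635, 7686 and 8801 (48 list calls, that of the housekeeping genes in BMM being lost at an adjusted p of 0.0647), and with the description numbers, which run from 2 to 4 for MPI-2 mock where the titles run from 1 to 3 and so leave fewer pairs, 1612 in MPI-2. With single arrays left out the counts ran from 4309 to 5562 for LPS in BMM, 2106 to 2463 in MPI-2, 2075 to 3025 for the difference, 6261 to 7305 for mock and 6994 to 9229 for LPS between cell types. The correlation of responses ran from 0.446 to 0.473 and list calls from 47 to 52. Without both doubted BMM arrays the counts were 5510, 4129, 3826, 7988 and 9339, with 51 list calls and a correlation of 0.429, against 0.465, whose cause was not tested. With an estimated correlation 21 of 49 list calls held. That test allows for genes of a list moving together, but such movement need not account for each lost call. The antigen presentation list in MPI-2 lost its call at an estimated correlation of 0.013, near the preset 0.01 (camera adjusted p = 0.0572). Signal over background limits the genes under 3.37, whose change within a cell type is compressed and whose difference of responses can be widened where 1 cell type alone is so limited.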

Other observations

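Genes of colony-stimulating factor signalling, transcription control and glycolysis moved one by one more than as lists. In BMM, LPS raised the STAT5 target Cish by log2 2.92 ± 0.23 (SE, n = 3 against 3), the kinase Jak2 by 2.83 ± 0.17, Stat5a by 2.23 ± 0.14, the granulocyte colony-stimulating factor receptor Csf3r by 1.64 ± 0.15 and the MiT family factor Tfec by 3.41 ± 0.17. In MPI-2, Jak2 rose by 1.89 ± 0.17, while Cish (0.00 ± 0.23), Csf3r (-0.02 ± 0.15) and Tfec (0.14 ± 0.17) did not pass, and each of these 3 had a lower response than in BMM (-2.92, -1.66 and -3.27), Csf3r from under background in MPI-2. In mock cells Cish was higher in MPI-2 by 3.85 ± 0.23 and Tfec by 3.56 ± 0.17, whereas the transcription factors Maf (-5.50 ± 0.22) and Mef2c (-3.95 ± 0.17) were lower. Cebpa, a myeloid transcription factor, fell after LPS by a larger size in BMM (-2.56 ± 0.18) than in MPI-2 (-0.91 ± 0.18; difference 1.64 ± 0.25), and Id1 fell in both (-1.52 ± 0.16 and -2.08 ± 0.16). The list of colony-stimulating factor signalling had 9 of 27 members higher and 7 lower in BMM and 8 and 7 in MPI-2, and neither passed camera (adjusted p = 0.147 and 0.261). The macrophage transcription factor list had 6 of 40 higher and 15 lower in BMM and 7 and 11 in MPI-2 (adjusted p = 0.0811 and 0.281).

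The vascular growth factor Vegfa fell after LPS in BMM by a larger size (-3.53 ± 0.17) than in MPI-2 (-0.74 ± 0.17; difference 2.79 ± 0.25), from a mock level of 9.69 ± 0.2 (SD, n = 3) in BMM and 6.47 ± 0.089 in MPI-2. Pfkfb3, which sets the rate of glycolysis, rose in BMM by 1.57 ± 0.13 and was at -0.01 ± 0.13 in MPI-2, and the oxygen-sensing hydroxylase Egln3 rose in MPI-2 by 1.56 ± 0.16. The hexose transporter Slc2a6 rose in both (2.58 ± 0.17 and 1.96 ± 0.17). The glycolysis and hypoxia list passed in neither (7 higher and 8 lower of 26 in BMM, adjusted p = 0.462, and 4 and 8 in MPI-2, adjusted p = 0.485). In mock cells the cytokines Lif (5.18 ± 0.17) and Il1f9 (4.92 ± 0.25) were higher in MPI-2, while the cytokine list did not pass (11 higher, 6 lower of 27, median 0.02, adjusted p = 0.142).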
